A study of Leymus chinensis with 14 samples.

How the data were processed

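Leaf total RNA of sheepgrass was sequenced in 14 libraries, prepared by Illumina's standard methods per the labels' protocols, which mention rice leaves in the extraction step. Per the submitters' processing notes the tools were Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0, and the genome build named is mm8, a mouse build, with no role or order given. How the transcripts were assembled and quantified is not given in the sources used here. The authors deposited 1 table with 1 row per assembled transcript, 1 abundance per library and annotation from protein databases. The unit is not named: the deposited values are not whole, never negative, and of a kind with TPM or FPKM, which differ by 1 factor per library. The table has 65536 lines with its header, the row limit of its format, and 4 broken lines were left out. It therefore holds part of the assembly, and no count, length or depth can be had from it. In transcripts that stay under 0.3 in every library, the log2 ratio of a library to check replicate 1 did not settle on steps of whole reads: of bins 0.1 wide the fullest held 3.7% to 7.8% of them. Whole reads were not recovered.

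All 14 sample columns matched a library name in the labels, and samples were grouped by their titles. The 65531 complete transcript rows belong to 29563 loci. The 3 loci reached by the edges of the table (17 transcripts) were left out. The values of the other 65514 transcripts were summed to 29560 loci, 19020 of them with 1 transcript. A locus takes its name from its most abundant annotated transcript. Names are database hits from other species and do not prove function, and near-identical copies may share reads.

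Loci with a value of at least 1 in at least 2 libraries were tested (20567) on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust), in 1 fit of 5 group means over all 14 libraries. P-values were adjusted by Benjamini-Hochberg within a comparison and loci with an adjusted p under 0.05 were called. The comparisons, the gene lists, the rule for named loci and the tests were fixed before the data were examined. The first choice of test assumed counts, and since the values are not counts the one set down for TPM-like values was used. The planned tests that need counts were not run. Summing transcripts to loci was decided after the table was seen. Of 8 comparisons 5 were main: high salt, low salt and low light against the normal-light check, high salt at low light, and the interaction.

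The 36 gene lists, matched by text in the annotation, were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and main comparisons together. The correlation estimated from the data and fry were alternatives. Camera compares a list with all other loci, and fry asks whether its loci move one way on balance. Named loci were chosen by a fixed rule: for a main comparison the 5 highest and 5 lowest described loci with an absolute log2 change of at least 1, a mean of at least 5 and no overlap between groups (except in the interaction). To these were added, for each list, the called member with the smallest p. For the other comparisons 3 and 3 were taken. Groups of 3 against 3 fail to overlap by chance for 10% of loci.

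The script was tested on simulated data with 200 changed loci among 20567. Noise was drawn from a normal distribution, independently for each locus at its fitted spread, so no correlation between loci and no outlying library was simulated. The shares below hold for that setting and may not hold for these libraries. For high salt at normal light it recovered 10.4%, 56.1% and 78.8% of loci changed by 1, 2 and 3 log2 units, and 7.1% of its calls were false. For high salt at low light, with 2 libraries, it recovered 6.3%, 45.7% and 70.9%. For the interaction it recovered 2.1%, 18.5% and 48.2%. Replicates correlated at 0.846 to 0.953 (log scale, across loci), and no 2 libraries of a group held identical values. Alternatives were median-of-ratios scaling, library totals, other filters, a pseudocount of 0.1, a fold minimum, only the groups compared, a replicate block and leaving out each library. Transcripts in place of loci, and leaving out loci with a fungal best hit (967 loci by genus, 196 of them tested), were added after seeing the data. Versions of other software were pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15.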

Results

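Transcript abundance was measured by RNA sequencing in leaves of sheepgrass (Leymus chinensis), a perennial forage grass of the Eurasian steppe, grown on a half-strength Murashige and Skoog medium and collected at 3 weeks of age. The 14 libraries fall into 5 groups. At normal light there were 3 libraries of a check group (labelled ck, with 0 in the salt position of the library name, and taken here as plants without added salt), 3 with low salt and 3 with high salt. At low light there were 3 check libraries and 2 with high salt. The salt concentrations and light levels are not given in the labels. The design text states the purpose as finding regulatory genes that respond to salt and to low light, and the series title names redox homeostasis under the combined stress. The labels call the samples replicates without saying whether each came from a separate plant, so p-values measure the spread between these samples, which may be technical.

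The deposited table gives 1 abundance per assembled transcript, summed here to 29560 loci (numbered g, as in the table), of which 20567 passed the filter on low values. The table stops at the row limit of its file format, so genes outside it are not analysed here. No read counts are given and the depth is unknown. The summed abundance of the complete rows ranged from 470162 to 581690 units per library, and the transcripts listed at 0 ranged from 10.3% to 18.5%. Locus names are those of the best database hit of 1 transcript of the locus. Fold changes are on the log2(value + 1) scale, which understates changes of scarce transcripts, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

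A small number of loci held much of the signal in the normal-light check libraries. The 100 loci with the highest mean abundance took 40.1% to 47.1% of each check library, against 26.9% to 36.8% with low salt, 26.0% to 32.2% with high salt at normal light and 23.5% to 29.5% across the 5 low-light libraries. Many loci near the top of this class had no description of function. Among these was the most abundant locus (g207486), at 27845, 20813 and 18205 in the check libraries. It stood at 7829, 10702 and 8892 with high salt at normal light. Described loci near the top included those for chlorophyll a-b binding proteins, photosystem subunits, Rubisco activase and the small subunit of Rubisco, the CO2-fixing enzyme. Others were a metallothionein, a mitochondrial glycine dehydrogenase and an extracellular ribonuclease (g79157). The ribonuclease stood at 640, 147 and 283 in the check libraries and at 4571, 7496 and 588 in the high-salt libraries at normal light (replicates 1, 2 and 3). Over all tested loci the median log2 change was 0.29 for high salt and 0.35 for low light against the check as deposited, and 0.04 and 0.05 after median-of-ratios scaling. The direction of calls turned with the scaling. For high salt, 613 loci were higher and 198 lower as deposited, and 160 higher and 407 lower after scaling. For low light the split was 2196 higher and 878 lower as deposited, and 762 higher and 1419 lower after scaling. List medians below are therefore given relative to the median of all loci.

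**Figure D1:**
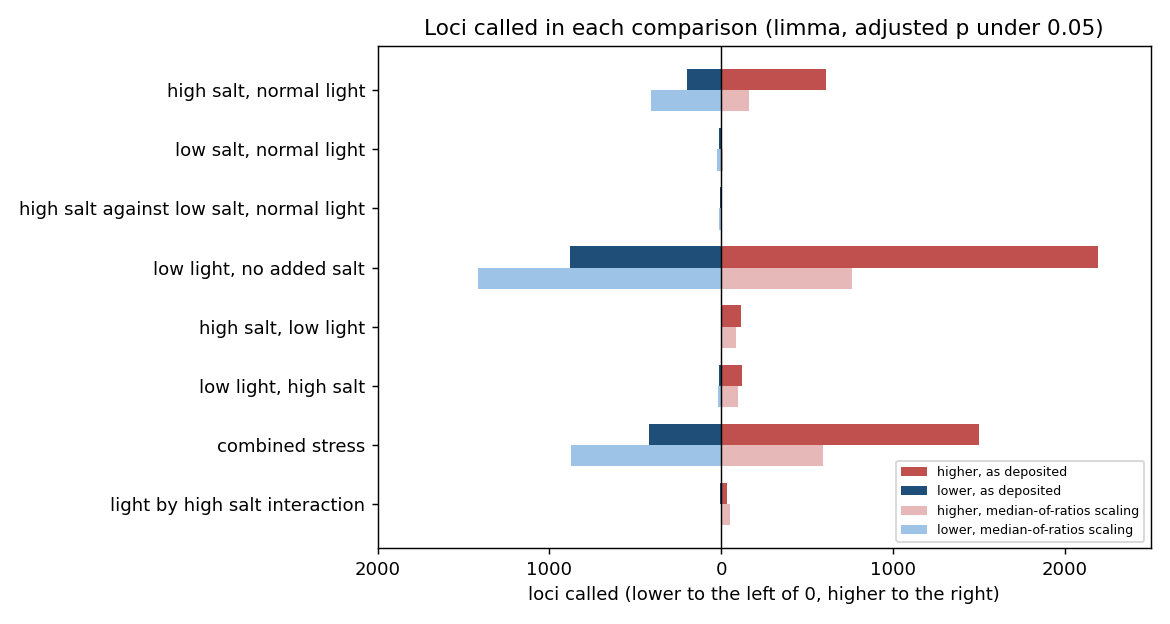
Loci called higher (right of 0) and lower (left of 0) in each comparison, on the horizontal axis in numbers of loci, as deposited (dark bars) and after median-of-ratios scaling (pale bars). Low light gives 2196 higher and 878 lower loci as deposited, and 762 and 1419 after scaling.

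High salt at normal light was compared with the check to ask which transcripts respond to salt alone. The 5 described loci with the highest folds under the fixed rule are given first. Pectinesterase inhibitor 8 (g98357), from a family that limits the removal of methyl groups from pectin, rose from 0.17 ± 0.13 to 59.2 ± 24.4 (mean ± SD, n = 3 each, log2 fold change 5.60, SE 0.62, limma adjusted p = 0.0061). Laccase-13 (g27393) and laccase-10 (g13265), from the family of copper oxidases that polymerise lignin precursors, rose to 46.7 ± 39.6 and 38.5 ± 27.5 from below 0.4 in the mean (SD, n = 3, limma adjusted p = 0.02 and 0.028). Wall-associated receptor kinase 2 (g9281), which spans the plasma membrane and the wall, rose from 0.254 ± 0.152 to 51.7 ± 55.2 (SD, n = 3). Wall-associated receptor kinase-like 2 (g87883) rose as well by 4.88 on the log2 scale (limma adjusted p = 0.047, and 0.063 after median-of-ratios scaling). The list for cell wall expansion had 1 of 25 loci higher and none lower, with 4 higher adjusted over the list alone and none after scaling (camera adjusted p = 0.33). The phenylpropanoid and flavonoid list, which holds laccase-13, had 5 of 96 higher and 2 lower, 8 and 4 adjusted over the list alone, and 3 and 3 after scaling (camera adjusted p = 0.53). The deposited median of that list was 0.29 and its mean 0.42, and camera's direction was down.

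Of 20 loci for abscisic acid synthesis and signalling 3 rose with high salt and none fell (8 rose adjusted over the list alone, and 2 after median-of-ratios scaling), and the list median was 0.66 above that of all loci. Its camera call (adjusted p = 0.028) was lost with an estimated correlation (adjusted p = 0.70). Protein phosphatase 2C 51 (g137880), of a family that acts in abscisic acid signalling, rose from 0.0448 ± 0.0482 to 1.76 ± 0.607 (SD, n = 3, limma adjusted p = 0.028). Among 30 loci for late embryogenesis abundant (LEA) proteins and dehydrins, which accumulate in drying tissue, 3 rose and none fell, with 14 rising adjusted over the list alone. The list median was 1.04 above all loci (camera adjusted p = 6.7e-04, and adjusted p = 0.57 with an estimated correlation). The called member with the smallest p was g144437, whose best hit is a UPF0098 protein, at 25.8 ± 18.9 against 1.18 ± 0.672 (SD, n = 3). Of 7 respiratory burst oxidases, the NADPH oxidases that make superoxide at the plasma membrane, 1 rose in the test over all loci and 5 rose adjusted over the list alone. That list gave a camera adjusted p = 0.028, and adjusted p = 0.75 with an estimated correlation. Homolog B (g92222) rose from 1.33 ± 0.238 to 7.65 ± 3.02 (SD, n = 3). Betaine aldehyde dehydrogenase 2 (g25145), which makes the osmolyte glycine betaine, rose from 20.7 ± 4.95 to 81.5 ± 17.6 (SD, n = 3, limma adjusted p = 0.017). The osmolyte list as a whole had 3 of 37 loci higher and none lower, 5 higher adjusted over the list alone and 1 higher after median-of-ratios scaling (camera adjusted p = 0.81). Its median lay at -0.03 relative to all loci, its mean at 0.12, and camera's direction was up.

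Of 37 antioxidant enzyme loci 3 were higher with high salt and none lower (5 higher adjusted over the list alone), with a camera adjusted p = 0.46, and none was called after median-of-ratios scaling. A superoxide dismutase (g25538) stood at 199 ± 77.6 against 57.0 ± 5.68 (SD, n = 3, limma adjusted p = 0.028, and 0.07 after scaling). Of 61 thioredoxin and glutaredoxin loci 4 were higher and none lower as deposited, 11 higher and 1 lower adjusted over the list alone, and none higher and 1 lower after scaling (camera adjusted p = 0.82). None of 42 glutathione S-transferases was called by limma (camera adjusted p = 0.51). Of 41 loci for sodium and potassium transport none was called as deposited or adjusted over the list alone, and 1 was lower after scaling (camera adjusted p = 0.64). Plasma membrane ATPase 1 (g21085), a proton pump, rose from 1.15 ± 0.328 to 4.46 ± 0.836 (SD, n = 3, limma adjusted p = 0.043, and 0.07 after scaling).

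Ribosomal protein and photosynthesis lists were compared with all other loci for high salt. Of 137 loci for cytosolic ribosomal proteins 50 rose and none fell (87 rose adjusted over the list alone), and 7 rose after median-of-ratios scaling. The list median was 0.88 above all loci (camera adjusted p = 1.6e-15, and adjusted p = 0.73 with an estimated correlation). 60S ribosomal protein L13-1 (g27922) rose from 76.7 ± 14.8 to 261 ± 28 (SD, n = 3). The 48 Calvin cycle loci had a median 1.18 below all loci, with 2 lower and 1 higher, 21 lower and 3 higher adjusted over the list alone, and 4 lower and 1 higher after scaling (camera adjusted p = 2.7e-08, and adjusted p = 0.21 with an estimated correlation). The called member with the smallest p, a transketolase (g20004), went the other way, from 1.27 ± 0.26 to 6.02 ± 1.36 (SD, n = 3). Photosystem and electron transport subunits had 4 of 93 loci lower and 1 higher (the same numbers adjusted over the list alone), and 8 lower and none higher after scaling, with a median 0.84 below all loci (camera adjusted p = 1.1e-14, and adjusted p = 0.24 with an estimated correlation). Without check replicate 1 or 3, or without high-salt replicate 1 or 2, no locus of this list was called lower. Ferredoxin--NADP reductase leaf isozyme 1 (g18235), the last enzyme of linear electron transport, fell from 498 ± 20.3 to 241 ± 14.3 (SD, n = 3, limma adjusted p = 0.03). Of 30 loci for photoprotection and carotenoids 3 fell, 4 adjusted over the list alone and 5 after scaling, with a median 0.96 below all loci (camera adjusted p = 1.2e-11, and adjusted p = 0.18 with an estimated correlation). Light-harvesting antenna loci had 2 of 43 lower and none higher, the same numbers adjusted over the list alone (camera adjusted p = 0.069). Their deposited median was 0.03 and their mean 0.14, and the median lay at -0.25 relative to all loci. Chlorophyll synthesis had none of 28 loci called by limma, 2 higher and 1 lower adjusted over the list alone, and 1 lower after scaling (camera adjusted p = 0.43). Phytoene synthase 2 (g26608), of the photoprotection and carotenoid list, the first committed enzyme of carotenoid synthesis, fell from 300 ± 41.9 to 96.9 ± 32.7 (SD, n = 3, limma adjusted p = 0.028). It stood at 86.2 ± 30.4 with low salt (SD, n = 3). Nitrate assimilation loci had 1 of 49 higher and 1 lower, none higher and 4 lower after scaling, and a median difference of -0.41 (camera adjusted p = 2.2e-03, and adjusted p = 0.24 with an estimated correlation). Photoreceptor and light signalling loci had none of 42 called by limma, 1 lower after scaling, and a median difference of -0.33 (camera adjusted p = 0.021, and adjusted p = 0.79 with an estimated correlation). Chlorophyll breakdown and senescence loci had 1 of 20 lower, 2 after scaling, and a median difference of -0.28 (camera adjusted p = 0.021, and adjusted p = 0.64 with an estimated correlation). The deposited median of this last list was 0.01 and its mean -0.15.

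The 5 described loci with the lowest folds for high salt under that rule were the following. The kinase PIX13 (g17812) fell from 154 ± 90.9 to 4.75 ± 7.89, beta-glucosidase 3 (g92910) from 62.2 ± 22.3 to 3.28 ± 2.97, and the kinase CRK6 (cysteine-rich receptor-like protein kinase 6, g200) from 95.0 ± 23.7 to 10.6 ± 8.9 (SD, n = 3). The related kinase CRK10 (g27266) stood at 17.1 ± 3.99 in the check (SD, n = 3) and was listed at 0 in all 3 high-salt libraries (limma adjusted p = 1.1e-05). CRK10 was also at or near 0 in the low-light groups, with and without salt. PIX13 stood at 3.96 ± 3.54 with low salt and at 4.38 ± 6.59 in the low-light check (SD, n = 3), so its low level was not particular to high salt. A disease resistance protein RGA1 locus (g216) fell from 31.7 ± 8.32 to 1.52 ± 0.557 (SD, n = 3). RGA1 is the best hit of 34 tested loci and CRK6 of 23, so reads may be split among near-identical copies of these. The pathogenesis-related list had 10 of 134 loci higher and none lower, with 19 higher adjusted over the list alone and 2 higher after median-of-ratios scaling (camera adjusted p = 0.039, and adjusted p = 0.53 with an estimated correlation). Its called member with the smallest p, S-adenosylmethionine synthase 1 (g23321), is an enzyme of methyl group supply and stood at 607 ± 110 against 300 ± 11.8 (SD, n = 3, limma adjusted p = 0.022, and 0.1 after scaling). In all, 811 of 20567 loci were called for high salt, and 358 of these were called in the same direction after scaling. The count fell to 24 without check replicate 1, 16 without check replicate 3, 69 without high-salt replicate 1 and 154 without high-salt replicate 2. Libraries outside the comparison enter through the shared spread, and the count was 528 without low-salt replicate 1, and 343 and 345 without replicates 1 and 2 of high salt at low light.

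**Figure D2:**
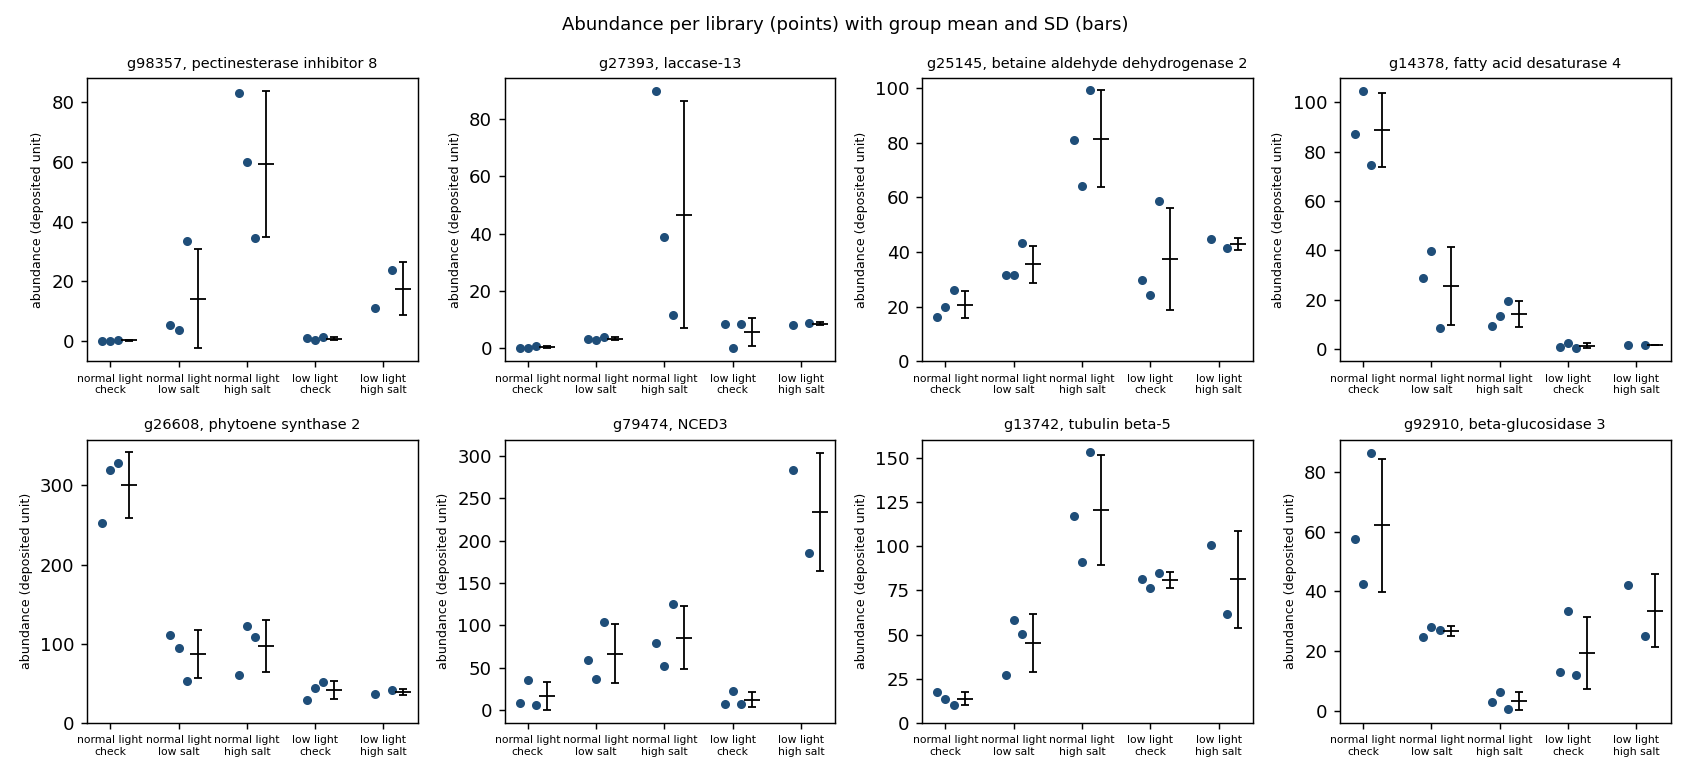
Abundance of 8 named loci in the deposited unit (vertical axes, linear) in each library (points), with the group mean and SD (bars), for the 5 groups on the horizontal axes. Phytoene synthase 2 lies at 300 ± 41.9 in the normal-light check and at 41.3 ± 11.7 in the low-light check, and NCED3 is highest in the 2 libraries with high salt at low light.

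Low salt at normal light gave few calls, 4 higher and 10 lower, and 10 higher and 27 lower after median-of-ratios scaling. At an unadjusted p under 0.05 there were 2466 loci. Vesicle-associated protein 2-1 (g18822), a membrane contact site protein, was listed at 0 in all check and all high-salt libraries at normal light and stood at 79.1 ± 54.6 with low salt (SD, n = 3, limma adjusted p = 3.2e-05). CRK10 fell to 0.026 ± 0.0263 and RGA1 locus g216 to 1.51 ± 0.663 (SD, n = 3), close to their high-salt levels. Both salt comparisons use the same check libraries. In the low-light check, without added salt, CRK10 stood at 0.00593 ± 0.0103 and g216 at 8.18 ± 6.4 (SD, n = 3). The low level of CRK10 was therefore not particular to salt. ABC transporter C family member 8 (g1392) fell from 34.6 ± 17.6 to 3.02 ± 2.71, and prolycopene isomerase (g19716), a carotenoid enzyme, from 22.8 ± 6.93 to 3.43 ± 1.3 (SD, n = 3, limma adjusted p = 0.038 and 0.02). With high salt they stood at 9.65 ± 3.62 and 6.76 ± 1.54, and in the low-light check at 1.43 ± 0.00132 and 5.04 ± 2.03 (SD, n = 3). Their low levels were therefore not particular to salt. An alpha-amylase (g23732) fell from 7.63 ± 4.41 to 0.15 ± 0.259 with low salt and to 0.0248 ± 0.0247 with high salt (SD, n = 3). It stood at 0.235 ± 0.128 in the low-light check (SD, n = 3), so this low level was not particular to salt either. The number of calls was 2 without check replicate 1, 6 without check replicate 3, 209 without check replicate 2, 78 without low-salt replicate 2 and 24 without low-salt replicate 1. It was 8 without high-salt replicate 1, and 9 and 23 without low-light check replicates 2 and 3.

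No list had more than 1 locus called with low salt over all loci. Abscisic acid loci had a median 0.57 above all loci (camera adjusted p = 0.009, and adjusted p = 0.58 with an estimated correlation), LEA proteins 0.41 above (camera adjusted p = 0.03, and adjusted p = 0.75 with an estimated correlation) and ribosomal proteins 0.65 above (camera adjusted p = 1.6e-15, and adjusted p = 0.73 with an estimated correlation). Calvin cycle loci had a median difference of -0.68 (camera adjusted p = 3.5e-09, and adjusted p = 0.18 with an estimated correlation), with 12 lower and 1 higher adjusted over the list alone. WRKY transcription factors stood 0.44 above all loci (camera adjusted p = 0.024, and adjusted p = 0.58 with an estimated correlation), with none of 30 called by limma over all loci and 2 higher adjusted over the list alone. Glutathione S-transferases stood 0.22 above (camera adjusted p = 0.047, and adjusted p = 0.80 with an estimated correlation). Lower were cell wall expansion (-0.41, camera adjusted p = 0.042, and adjusted p = 0.82 with an estimated correlation), photoprotection and carotenoids (-0.35, camera adjusted p = 1.5e-03, and adjusted p = 0.57 with an estimated correlation), nitrate assimilation (-0.26, camera adjusted p = 9.4e-03, and adjusted p = 0.33 with an estimated correlation) and photosystem subunits (-0.17, camera adjusted p = 3.7e-03, and adjusted p = 0.79 with an estimated correlation). Antioxidant enzymes gave a camera adjusted p = 0.93, thioredoxins and glutaredoxins 0.69 and osmolyte enzymes 0.18.

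The 2 salt levels were compared with each other at normal light, and 2 loci were higher and 8 lower with high salt. Polyubiquitin (g86732) stood at 9.31 ± 0.675 with high salt and 35.5 ± 6.17 with low salt, and the zinc finger protein ZAT5 (g90674) at 1.51 ± 1.73 and 27.0 ± 16.7 (SD, n = 3, limma adjusted p = 0.009 and 0.044). At an unadjusted p under 0.05 there were 2219 loci. Without high-salt replicate 3 the count was 223, without high-salt replicate 1 it was 16, without low-salt replicate 2 it was 49 and without low-salt replicate 1 it was 4. Of libraries outside this comparison, check replicates 1, 2 and 3 gave 3, 6 and 3 when left out, and low-light check replicates 2 and 3 gave 5 and 6. On the second principal component (12.5% of the variance) high-salt replicate 3 lay at 2.0, and high-salt replicates 1 and 2 at -77.8 and -72.1.

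Low light without added salt gave 3074 calls, and 1438 when fitted with only the groups compared. Photosynthesis transcripts were among those that fell. Of 93 photosystem and electron transport loci 36 fell and none rose (47 fell adjusted over the list alone, and 53 after median-of-ratios scaling), with a median 1.16 below all loci. Leaving out 1 library of the groups compared gave 21 to 32 that fell. The camera adjusted p = 2.3e-24 was lost with an estimated correlation (adjusted p = 0.18). A carboxyl-terminal-processing peptidase 3 (g16535), from the family that matures a photosystem II core protein, fell from 44.8 ± 6.6 to 6.03 ± 4.96 (SD, n = 3, limma adjusted p = 0.002). Of 43 light-harvesting antenna loci 6 fell and none rose (4 fell adjusted over the list alone, and 9 after scaling), with a median 0.87 below all loci (camera adjusted p = 1.7e-04, and adjusted p = 0.73 with an estimated correlation). Of 30 photoprotection and carotenoid loci 12 fell and none rose (16 fell adjusted over the list alone, and 17 after scaling), with a median 1.31 below (camera adjusted p = 1.9e-12, and adjusted p = 0.18 with an estimated correlation). Phytoene synthase 2 fell from 300 ± 41.9 to 41.3 ± 11.7 (SD, n = 3, limma adjusted p = 0.0012). Calvin cycle loci had 9 of 48 lower and 2 higher, 19 lower and 7 higher adjusted over the list alone, 17 lower and 2 higher after scaling, and a median difference of -0.92 (camera adjusted p = 2.1e-05, and adjusted p = 0.33 with an estimated correlation). The called member with the smallest p was a chaperonin 60 subunit (g19029), a protein-folding factor of the chloroplast, which rose from 25.4 ± 7.13 to 77.8 ± 11.8 (SD, n = 3).

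Fatty acid desaturase 4 (g14378), which makes an unusual fatty acid of chloroplast phosphatidylglycerol, fell from 88.7 ± 15 to 1.35 ± 1.06, and the plastid transcription factor sigE (g27029) from 96.7 ± 25.4 to 2.51 ± 1.91 (SD, n = 3, limma adjusted p = 4e-04 for both). A MYB-related protein (g1767) fell from 118 ± 35.4 to 3.45 ± 3.23, and a sulfurtransferase (g83941) from 45.4 ± 33.6 to 0.00501 ± 0.00868 (SD, n = 3). PIX13 fell to 4.38 ± 6.59 (SD, n = 3). Nitrate assimilation loci had 8 of 49 lower and 5 higher (12 and 5 adjusted over the list alone, and 13 and 4 after scaling), with a median 1.03 below all loci (camera adjusted p = 6.9e-05, and adjusted p = 0.18 with an estimated correlation). The transporter NRT1/PTR family 6.4 (g8007) fell from 51.8 ± 13.1 to 1.97 ± 1.34 (SD, n = 3, limma adjusted p = 0.002). Chlorophyll synthesis loci had 6 of 28 higher and 3 lower, 8 and 3 adjusted over the list alone, and 2 higher and 4 lower after median-of-ratios scaling (camera adjusted p = 0.87). Sucrose, starch and fructan loci had 8 of 73 lower and 5 higher (9 and 6 adjusted over the list alone, 11 and 2 after scaling, camera adjusted p = 0.24), and sucrose-phosphate synthase 5 (g81955), a sucrose-making enzyme, fell from 59.9 ± 8.8 to 12.6 ± 5.55 (SD, n = 3). Phenylpropanoid and flavonoid loci had 13 of 96 lower and 2 higher, 13 and 3 adjusted over the list alone, and 19 and none after scaling (camera adjusted p = 0.011, and adjusted p = 0.63 with an estimated correlation). Their deposited median was 0.22, against a deposited mean of -0.03, and lay at -0.13 relative to all loci. Chlorophyll breakdown and senescence loci had 3 of 20 lower, also adjusted over the list alone, 4 after scaling, and a median difference of -0.48 (camera adjusted p = 0.021, and adjusted p = 0.64 with an estimated correlation). Jasmonate loci had 4 of 51 lower and 1 higher, 2 and 1 adjusted over the list alone, 5 and 1 after scaling, and a median difference of -0.36 (camera adjusted p = 0.022, and adjusted p = 0.73 with an estimated correlation). Linoleate 9S-lipoxygenase 1 (g22292) fell from 64.5 ± 12.2 to 14.7 ± 0.376 (SD, n = 3). A 60 kDa jasmonate-induced protein (g16570), among the 5 described loci with the highest folds at low light, went the other way. It rose from 0.711 ± 1.23 to 62.8 ± 58.6 (SD, n = 3, limma adjusted p = 0.016).

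Of 137 loci for cytosolic ribosomal proteins 83 rose at low light and none fell (90 rose adjusted over the list alone), 64 rose and none fell after median-of-ratios scaling, and the median was 1.25 above all loci (camera adjusted p = 3.7e-20, and adjusted p = 0.64 with an estimated correlation). L13-1 reached 397 ± 74.8 (SD, n = 3). The ethylene-responsive factor RAP2-6 (g27902) rose from 0.899 ± 0.637 to 31.0 ± 4.72 (SD, n = 3, limma adjusted p = 2.1e-04), and 8 of 41 ERF and DREB factors rose with none lower, 9 adjusted over the list alone, and 7 higher and 1 lower after scaling (camera adjusted p = 0.17). Auxin-responsive protein IAA6 (g14289) rose from 10.6 ± 2.31 to 35.9 ± 5.56, and NAC factor 21/22 (g14902) from 0.799 ± 0.905 to 7.86 ± 0.724 (SD, n = 3). A trehalose-phosphate synthase (g15925) rose from 14.2 ± 6.65 to 92.7 ± 12.5, and a vacuolar proton-pumping pyrophosphatase (g15564) from 63.7 ± 14.2 to 216 ± 68.8 (SD, n = 3). Pathogenesis-related loci had 24 of 134 higher and 7 lower, 33 and 10 adjusted over the list alone, and 11 and 13 after scaling (camera adjusted p = 0.47). Photoreceptor and light signalling loci had 7 of 42 higher and 3 lower, 9 and 5 adjusted over the list alone, and 4 and 8 after scaling (camera adjusted p = 0.65). A coatomer subunit beta' locus (g9956), from the coat of Golgi vesicles, was listed at 0 in all 3 check libraries and stood at 27.5 ± 17.5 at low light (SD, n = 3). At normal light it stood at 14.3 ± 12.4 with low salt and 3.79 ± 5.24 with high salt (SD, n = 3). Its best hit is shared by 14 tested loci, so this locus does not stand for the subunit as a whole.

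Of 37 antioxidant enzyme loci 10 rose at low light and none fell as deposited, 13 rose and 1 fell adjusted over the list alone, and 3 rose and 2 fell after median-of-ratios scaling (camera adjusted p = 0.21). Superoxide dismutase locus g20282 rose from 17.6 ± 3.25 to 72.5 ± 30.4 (SD, n = 3, limma adjusted p = 0.0048, and 0.02 after scaling). Thioredoxin and glutaredoxin loci had 6 of 61 higher and 4 lower, the same numbers adjusted over the list alone, and 2 higher and 9 lower after scaling (camera adjusted p = 0.63). Their median lay at -0.03 and their mean at 0.01 relative to all loci. Thioredoxin M3 (g23755), a chloroplast form, fell from 47.8 ± 9.82 to 13.6 ± 5.56 (SD, n = 3). Glutamate--cysteine ligase (g81950), the first enzyme of glutathione synthesis, was called higher (limma adjusted p = 0.035), and not after scaling (adjusted p = 0.45). Among 22 circadian clock loci 5 rose and 3 fell (6 and 4 adjusted over the list alone), and 2 rose and 4 fell after scaling (camera adjusted p = 0.65). GIGANTEA locus g98846 rose from 16.9 ± 1.43 to 38.4 ± 0.414 (SD, n = 3). The count of loci for low light fell from 3074 to 1187 without check replicate 1 and to 1414 without check replicate 3.

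**Figure D3:**
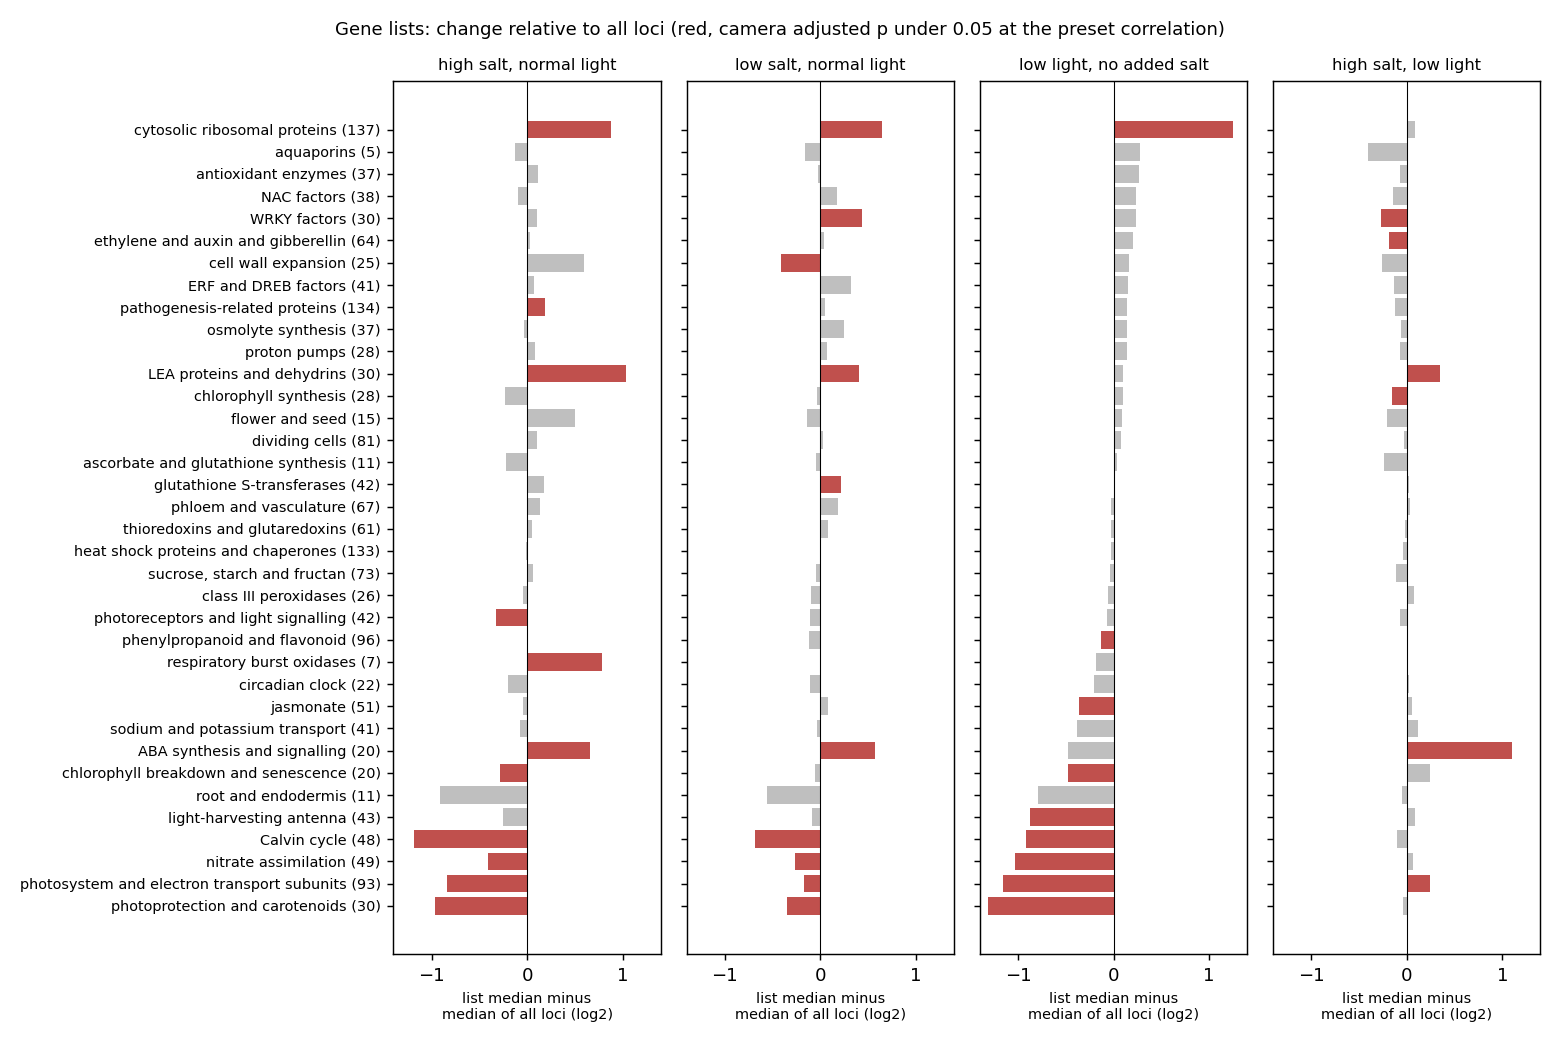
Median log2 change of each fixed gene list minus the median of all loci (horizontal axes, log2 units) in 4 comparisons, with the number of tested loci in brackets. Red bars passed camera at the preset correlation, and none passed with an estimated correlation. Photoprotection and carotenoids lies at -1.31 and cytosolic ribosomal proteins at 1.25 for low light.

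High salt at low light was compared with the low-light check to ask what salt adds once light is low. NCED3 (g79474), the 9-cis-epoxycarotenoid dioxygenase that limits abscisic acid synthesis, rose from 12.6 ± 8.9 (SD, n = 3) to 234 ± 69.6 (SD, n = 2), with limma adjusted p = 0.016. Its mean was also higher with salt at normal light. There it stood at 16.6 ± 16.1 in the check, 66.8 ± 34.7 with low salt and 85.5 ± 37.4 with high salt (SD, n = 3). The abscisic acid list had 1 of 20 loci higher, 11 higher and 1 lower adjusted over the list alone, and a median 1.10 above all loci (camera adjusted p = 1.6e-05, and adjusted p = 0.24 with an estimated correlation). Gibberellin 2-beta-dioxygenase 6 (g27565), which inactivates gibberellins, stood at 3.9 ± 1.77 in the low-light check (SD, n = 3) and was listed at 0 in both high-salt libraries. The kinase CHARK (g13731) fell from 17.3 ± 6.49 (SD, n = 3) to 3.62 ± 0.605 (SD, n = 2). Disease resistance protein RGA5 (g1838) rose from 0.169 ± 0.108 (SD, n = 3) to 28.1 ± 17.0 (SD, n = 2), and is the best hit of 56 tested loci. Photosystem I reaction center subunit IV (g94898) rose from 67.2 ± 6.4 (SD, n = 3) to 250 ± 27.7 (SD, n = 2), with limma adjusted p = 0.048 and 0.06 after median-of-ratios scaling. The best hit of g94898 is shared by 5 tested loci. A more abundant locus of that name (g80301) stood at 2458, 2867 and 3115 in the low-light check. With high salt at low light g80301 stood at 2635 and 5274, so the rise of g94898 does not stand for the subunit as a whole. The 93 photosystem loci had a median 0.24 above all loci (camera adjusted p = 0.0088, and adjusted p = 0.82 with an estimated correlation). WRKY factors had a median difference of -0.27 (camera adjusted p = 0.011, and adjusted p = 0.53 with an estimated correlation). LEA proteins and dehydrins lay 0.35 above (camera adjusted p = 0.028, and adjusted p = 0.75 with an estimated correlation). Ethylene, auxin and gibberellin loci had 1 of 64 lower, 3 adjusted over the list alone, and a median difference of -0.19 (camera adjusted p = 0.019, and adjusted p = 0.73 with an estimated correlation). Chlorophyll synthesis had a median difference of -0.16 (camera adjusted p = 0.026, and adjusted p = 0.77 with an estimated correlation). None of the 37 antioxidant enzymes was called by limma, over all loci or adjusted over the list alone (camera adjusted p = 0.67).

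In all 114 loci were called higher and 4 lower with high salt at low light. Of the higher loci 78 had no description and no fungal hit, 2 had a best hit to a fungus, and 54 stood below 0.5 in all 12 other libraries. With the filter set at a value of at least 1 in 3 libraries, which removes loci seen in 2 libraries alone, 12 were higher and 3 lower. Without either low-light high-salt library, 10 loci (without replicate 1) or 2 loci (without replicate 2) passed the threshold.

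Low light was also compared with normal light among plants given high salt, where 122 loci were higher and 13 lower. Of the higher loci 74 had no description and no fungal hit, 9 had a best hit to a fungus and 39 were described without one. With the filter set at a value of at least 1 in 3 libraries 6 were higher and 3 lower. Jacalin-related lectin 3 (g22740) fell from 29.5 ± 11.4 (SD, n = 3) to 2.85 ± 0.699 (SD, n = 2), and cation/calcium exchanger 1 (g19687) from 7.48 ± 1.58 (SD, n = 3) to 2.22 ± 0.117 (SD, n = 2), with limma adjusted p = 0.0036 and 0.03. Syntaxin-132 (g20298), a membrane fusion protein, rose from 4.12 ± 2.43 (SD, n = 3) to 35.0 ± 8.53 (SD, n = 2), and its adjusted p of 0.049 became 0.072 after median-of-ratios scaling. The count was 2 without either low-light high-salt library, 79 without high-salt replicate 2 at normal light, and 285 without low-salt replicate 2, which is outside the comparison.

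The combined stress, low light with high salt against the normal-light check, gave 1504 higher and 423 lower loci, and 594 higher and 874 lower after median-of-ratios scaling. Plastocyanin (g98084), the copper carrier of photosynthetic electron transport, fell from 1500 ± 660 (SD, n = 3) to 88.4 ± 102 (SD, n = 2), with limma adjusted p = 0.014. Fatty acid desaturase 4 fell to 1.64 ± 0.038 (SD, n = 2). Dormancy-associated protein homolog 1 (g96690) rose from 0.0128 ± 0.017 (SD, n = 3) to 43.9 ± 24.3 (SD, n = 2), and cold shock protein CS66 (g81858), a dehydrin, from 1.83 ± 1.33 (SD, n = 3) to 73.5 ± 74.7 (SD, n = 2). The calls fell to 13 without low-light high-salt replicate 1 and to 318 without replicate 2, and to 557 and 716 without check replicates 1 and 3.

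Whether the response to high salt differed between light levels was tested as an interaction, and 36 loci were above 0 and 7 below as deposited, and 52 and 3 after median-of-ratios scaling. Of the 36 loci above 0, 26 had no description and no fungal hit. With the filter set at a value of at least 1 in 3 libraries, which removes loci seen in 2 libraries alone, 5 loci were called, all above 0. Tubulin beta-5 (g13742) was 13.6 ± 3.76 in the normal-light check and 121 ± 31.2 with high salt (SD, n = 3). At low light it was 81.0 ± 4.34 (SD, n = 3) without and 81.3 ± 27.6 (SD, n = 2) with high salt, an interaction of -3.10 (SE 0.47, limma adjusted p = 0.022, and 0.016 to 0.28 over its alternatives). Beta-glucosidase 3 fell with high salt at normal light and stood at 19.4 ± 12 (SD, n = 3) and 33.6 ± 12.2 (SD, n = 2) without and with it at low light (interaction 4.97, limma adjusted p = 0.028, and 0.012 to 0.26 over its alternatives). Neither interaction passed with a value of at least 1 in 3 libraries (limma adjusted p = 0.074 and 0.082), a pseudocount of 0.1 (0.055 and 0.079) or a replicate block (0.093 for both), and no locus below 0 was called under these 3. Photosystem loci had an interaction median 1.00 above all loci (camera adjusted p = 4.6e-14, and adjusted p = 0.24 with an estimated correlation), with none of 93 called over all loci and 19 higher adjusted over the list alone. Also above all loci were the Calvin cycle (1.00, camera adjusted p = 2.1e-03, and adjusted p = 0.57 with an estimated correlation), chlorophyll breakdown (0.91, camera adjusted p = 2.1e-03, and adjusted p = 0.53 with an estimated correlation) and photoprotection (0.88, camera adjusted p = 6.7e-07, and adjusted p = 0.24 with an estimated correlation). Below were ribosomal proteins (-0.84, camera adjusted p = 1.1e-07, and adjusted p = 0.82 with an estimated correlation), respiratory burst oxidases (-0.80, camera adjusted p = 0.038, and adjusted p = 0.75 with an estimated correlation) and pathogenesis-related proteins (-0.27, camera adjusted p = 0.015, and adjusted p = 0.33 with an estimated correlation). The count of calls was 5 without low-light high-salt replicate 1, 4 without replicate 2, 157 without check replicate 2 and 123 without high-salt replicate 3 at normal light. It was 81 without low-light check replicate 1, and 23 and 24 without check replicates 1 and 3 at normal light.

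Across the 20567 loci the log2 changes for high salt at low light and at normal light had a Pearson correlation of 0.05 and a Spearman correlation of 0.03. The correlation is across genes, which are not independent replicates, and no library is shared. Independent noise in both sets of changes lowers such a correlation, and high salt at low light rests on 2 libraries. What value like responses would give here was not tested. A low correlation therefore does not show that the responses differ. Pearson's value ranged from -0.02 without low-light check replicate 2 to 0.13 without low-light check replicate 3. High salt at normal light and low light without salt shared 380 higher and 156 lower calls (58 and 339 after scaling), and 3 calls had opposite signs, against 65.5 and 8.45 for independent lists of those lengths. These comparisons share the check libraries. In 100 simulated sets of unchanged groups the median number of shared calls was 0 and the highest 2. Unchanged groups should give few calls, so these numbers are no chance value for lists this long. The log2 changes had a Pearson correlation across genes of 0.60, within the -0.15 to 0.86 of the simulations (mean 0.47). The covariance of the fold changes was 0.41, against 0.16 in the mean of the simulations, where the highest was 0.32. High salt and low salt shared 9 lower calls and no higher call (24 and 1 after scaling), against 0.0963 and 0.119 for independent lists. Their correlation across genes was 0.58, within the simulated -0.39 to 0.79 (mean 0.46). Their covariance of 0.304 stood beside a simulated mean of 0.149 and a highest simulated value of 0.302. No split of 3 check libraries leaves 2 in each part, and none was run, so part of any excess may come from them.

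None of the lists for dividing cells, root and endodermis, phloem and vasculature, or flower and seed passed camera in any of the 5 main comparisons. The lowest camera adjusted p was 0.07, for the 11 root and endodermis loci with high salt at normal light, of which 1 was lower. At low light 7 of 81 loci for dividing cells were higher and 1 lower, and 7 of 67 for phloem and vasculature higher and 3 lower, and after median-of-ratios scaling none and 2, and 4 and 4. Fry, which asks whether a list moves one way as deposited and not whether it differs from other loci, called dividing cells higher with high salt and at low light (adjusted p = 3.4e-03 for both) and lower in the interaction (0.033). It called phloem and vasculature higher with high salt and at low light (adjusted p = 2.3e-03 for both) and with low salt (0.014), and lower in the interaction (0.011). Of the 84 loci matched to that list before the filter, 48 matched by a protein domain (Pfam) alone. Its called members with the smallest p were aspartyl proteases (g22893 with high salt and g24970 at low light). Those of dividing cells were cyclin-dependent kinases F-4 (g20055) and C-1 (g21815). These calls do not show a larger share of either tissue. The summed abundance of transcripts with a best hit to a fungus was not tested between groups. It was 217 ± 31.9 in the normal-light check, 627 ± 416 with low salt, 505 ± 74.9 with high salt and 868 ± 514 in the low-light check (SD, n = 3), and 1688 ± 395 with high salt at low light (SD, n = 2). Loci with a fungal best hit made up 108 of the 1504 higher calls of the combined stress and 10 of the 2196 of low light.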

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

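The interaction test was planned, and the tests with abundant loci taken out, of the fungal ratio, of library pairs, of the photosystem list against all loci, of clock loci and of other splits were chosen after the results were seen, as were their thresholds and the list of fungal genera. The response to high salt differed between light levels for 43 loci by the interaction test, and those named by the fixed rule were beta-glucosidase 3 (4.97), ABC transporter C family member 8 (4.27), tubulin beta-5 (-3.10), a tubulin alpha chain (-2.79), phosphoenolpyruvate/phosphate translocator 1 (-2.38), the B3 domain protein IDEF1 (-1.79) and the beta subunit of pyrophosphate-dependent phosphofructokinase (-1.58), in log2 units. After median-of-ratios scaling 3 of these 7 were called, and the tubulin alpha chain, the translocator, IDEF1 and the phosphofructokinase were not (limma adjusted p = 0.05, 0.063, 0.063 and 0.059). None of the 7 passed with a value of at least 1 in 3 libraries, a pseudocount of 0.1 or a replicate block. Among the 36 loci above 0, 26 had no description and no fungal hit. A value of at least 1 in 3 libraries left 5 of any kind called, so the count of 43 rests largely on that filter. At the preset correlation 7 lists differed too, with medians relative to all loci of 1.00 for the Calvin cycle, 1.00 for photosystem subunits, 0.91 for chlorophyll breakdown, 0.88 for photoprotection, -0.84 for ribosomal proteins, -0.80 for respiratory burst oxidases and -0.27 for pathogenesis-related proteins. None of these list calls held with an estimated correlation. Fungal transcripts, which no comparison was about, summed to 1966.5 and 1408.5 in the 2 libraries with high salt at low light, against 1364.2 in low-light check replicate 2, 1106.3 in low-salt replicate 2 and at most 238 in the normal-light check.

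As deposited, more loci were higher than lower against the normal-light check for high salt, low light and the combined stress. For low salt 4 were higher and 10 lower, and after median-of-ratios scaling more were lower in all 4 of these comparisons. If the abundant transcripts of the check set this split, taking out the most abundant loci and scaling the rest to 1 total would lower the median change. The loci taken out were of any kind, and many had no description, so photosynthesis transcripts were not tested apart. The low-light median was 0.457 with no locus taken out, 0.388 with 10, 0.211 with 100 and 0.124 with 500, against 0.345 as deposited (first run with 100 loci and then widened). The shift shrinks step by step and how much is left depends on how many loci are taken out, so a share effect of abundant transcripts and a broad rise of the other transcripts cannot be told apart without a spike-in.

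The loci higher with high salt at low light are mostly undescribed (70.2% against 39.0% of tested loci). Reads from the fungi seen elsewhere stay open, and other organisms were not tested: low-salt replicate 2 holds fungal loci at a median ratio of 0.741 to the low-light high-salt mean, and the third quartile of that ratio over the 114 called loci was 0.067 (taken because their median is 0), but of the 6 salt libraries at normal light it is the 1 where that fungal median reaches 0.1. Plants of another genotype may carry genes that the others lack, and 10 loci were present (at least 5) in this pair of libraries alone and below 0.5 in the other 12. The highest number for a pair from different groups was 4, and check replicates 1 and 3 shared 15. A treatment response in these plants would give the same count, so genotype and treatment cannot be told apart here.

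Photosystem loci had lower medians than all loci at low light and with high salt, a call that was lost with an estimated correlation. A smaller share of abundant transcripts would raise other loci alike, so it would not by itself put a list below all loci. The list was picked for that difference in these same data, so the values describe it and are no separate test of that cause. The list median was -0.81 at low light (-0.92 to -0.80 without each library compared), against 0.35 for all loci. With high salt it was -0.55 (-0.66 to -0.45), against 0.29. The list median lay below that of all loci in 9 of 9 library pairs in each, which re-pair the same libraries. Fry called the list lower as deposited (adjusted p = 2.3e-03 and 0.049). A first form of this comparison, on the loci called lower (36, and 4 with high salt), had left high salt open. Sampling at another time of day stays open. Clock loci were called for low light in 36.4% of cases, against 14.9% of other loci (Fisher's exact test, two-sided, p = 0.011). That test takes loci as independent, but all were measured in the same libraries and several called clock loci share the name GIGANTEA. These may be copies of the same gene, so the p-value may be too small. Light itself also sets the clock, so time of day and the treatment cannot be told apart. A response to low light, the variable of the design, is untested beyond the comparison itself.

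Other splits of the same 6 libraries gave fewer calls for high salt (at most 6, against 811 in 1 of 10 splits), low salt (13 against 14), high against low salt (6 against 10) and low light (11 against 3074). For lists the highest other split called 9 against 11 for high salt, 9 against 10 for low salt and 11 against 9 for low light, where 2 of 10 splits called as many. With 10 splits no share under 0.05 is possible. A split that mixes the groups also puts any difference between them into the spread, which lowers its calls. The counts of the other splits are therefore no chance level.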

How the results depend on the processing

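Tests on transcripts in place of loci, lists and overlaps with median-of-ratios scaling, overlaps with a replicate block, and fits without fungal loci were chosen after the data were seen. The planned count-based tests (a quasi-likelihood, a Wald and a voom test) were not run, as no counts are given, and depth is unknown. No named locus changed sign, and no list call passed in the opposite direction. Of refits, 435 of 1765 for 117 named results and 129 of 774 for 43 list calls no longer passed. A list that changed direction without passing is counted among the latter. Counts of calls moved as follows, and the cause was not tested except where given. Median-of-ratios scaling gave 37 for low salt and 25 shared with high salt, and library totals 1279 for high salt. Without a filter there were 366 for high salt, 259 for high salt at low light, 323 for low light at high salt and 132 for the interaction. A value of at least 1 in 3 libraries, which by construction drops loci seen in 2, gave 27 for low salt and, in the other 3, 15, 9 and 5. A pseudocount of 0.1 gave 69, 58 and 9 in those 3. With only the groups compared, and so fewer libraries, there were 462 for high salt, 3 for high against low salt, 1438 for low light, 4 for high salt at low light, 12 for low light at high salt and 3097 for the combined stress. Transcripts gave 1267 for high salt, 29 for low salt, 7700 for low light, 3843 for the combined stress and 67 for the interaction. An estimated correlation left 0 lists in each main comparison, and fry called 5 for low salt, 14 for low light and 1 for high salt at low light. Without fungal loci no count moved by over 1.5 times.

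With the replicate block there were 408 calls for high salt, 22 for low salt, 19 for high against low salt, 76 for high salt at low light, 58 for low light at high salt and 23 for the interaction, and 278 shared by high salt and low light. Same-numbered libraries correlated at -0.17 to 0.15 over 26 pairs in their deviations, and 6 of 14 libraries correlated best with their own number. These values show no strong pairing by number. They cannot exclude a weaker pairing or batch, and the labels do not say whether the numbers pair the samples.

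Leaving out 1 library of the groups compared gave 16 to 1116 calls for high salt, 2 to 209 for low salt, 4 to 223 for high against low salt, 1187 to 2874 for low light, 2 to 109 for high salt at low light, 2 to 184 for low light at high salt, 13 to 1782 for the combined stress and 4 to 157 for the interaction. Lists called ranged over 9 to 11, 5 to 11, 6 to 10, 4 to 10 and 6 to 10 for high salt, low salt, low light, high salt at low light and the interaction. The correlation of salt responses ranged from -0.019, without low-light check replicate 2, to 0.126. Where 1 of the 2 libraries with high salt at low light is left out, the lone sample is assumed to vary like the other groups.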

Other observations

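Except for g98846, the loci named here were chosen after their values were seen. Clock loci changed in both directions at low light. All 4 called GIGANTEA loci were higher (g98846, g85206, g136478 and g82379, by 1.14, 1.38, 1.58 and 1.33 log2 units), and so was the response regulator PRR1 (g16290, 1.75, limma adjusted p = 0.024). REVEILLE 1-like (g19999) was lower by the test (-3.38, limma adjusted p = 0.0066), as were 2 REVEILLE 6 loci (g99491 and g98118, -1.45 each). GIGANTEA and PRR1 peak toward evening in other plants and the REVEILLE factors near dawn, and after median-of-ratios scaling 2 clock loci were higher and 4 lower.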
